A study of Homo sapiens with 4 samples.

How the data were processed

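RNA was measured in 4 libraries of trophoblast cells derived from human embryonic stem cells. There was 1 for each of the lines ENVY and H9 on day 3 of BAP differentiation. Another 1 for each came from day 15, after further culture under trophoblast stem cell conditions. The groups, days and lines come from the labels. Per the labels, messenger RNA was extracted with a column kit and libraries followed a standard Illumina protocol. Per the submitters' processing notes, HISAT2 was the aligner named and hg38 the genome build, and no version was given. The counting tool, the annotation and the strand setting are not given in the sources used here.

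The deposited table holds counts per gene symbol, although its name announces FPKM. All values are whole (100%), the totals differ between libraries, from 8327169 to 10350354, and with genes ranked by length into 10 bins, the median value of the longest bin was 3.83 to 5.02 times that of the shortest bin, which a length-normalized unit would remove. The values were therefore treated as raw counts, and edgeR's quasi-likelihood test replaced the limma fit on log2(FPKM + 1) that had been fixed before the data were examined. The table had 28278 rows, of which 6532 were 0 in every library, and 26998 symbols matched the RefSeq table of GRCh38.p14, the source of the coordinates given. Sex-linked marker genes (69 rows) were left out of every step. No mitochondrially encoded gene was in the table, so that list of 13 genes was not analysed.

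Genes with at least 1 CPM in at least 2 libraries were tested, 15082 in all. Library sizes were scaled with TMM, whose factors were 1.07 for ENVY and 1.01 for H9 at day 3 and 0.991 for ENVY and 0.934 for H9 at day 15. Levels are CPM on these scaled sizes, and differences within a line or between 2 libraries are in log2(CPM + 1), which understates the change of low genes. Stage was fitted with edgeR 4.0.16 over all 4 libraries with no covariate, and the lines were compared with stage as a covariate. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.552 in the stage fit. The standard error of a log2 change was taken as its size divided by the square root of edgeR's F. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for the 31 of 32 lists with at least 5 tested members, and 874 of their 888 members were in the table.

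The genes named were fixed by a rule before the data were examined. For the stage comparison they are the 12 with the largest difference each way in log2(CPM + 1), in the same direction in both lines and with at least 5 CPM in the higher group, and for the lines the 5 each way. The rule asked for an adjusted p under 0.05, and since no gene reached it, the rule's fallback names the largest differences with values only. A set of 16 marker genes is given whatever its values. No list member passed over all genes, so the examples of each list are the 2 with the highest mean CPM.

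The replicate number stands for the cell line in both groups, so the numbers pair the libraries, and cell line was used as a block in an alternative fit. As a check, the correlation across genes of the H9 deviation from the group mean at day 3 with that at day 15 was -0.0162. The labels do not say whether cultures were repeated, so p-values of single genes measure the spread between these libraries. Camera's p at the preset correlation rests mainly on the spread across genes and does not measure the spread between libraries.

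Each test was also run on simulated counts with the real means and library sizes and 200 changed genes among 15082. At the spread estimated from the 4 libraries, edgeR recovered 99 of 100 genes changed 64-fold and 18 of 100 changed 4-fold in the stage comparison, with 5 false calls, and DESeq2 recovered 96 and 36, with 46 false calls. In the line comparison edgeR recovered 99 and 21 with 2 false calls, and DESeq2 98 and 31 with 27. For a list of unchanged genes camera's unadjusted p was 0.0358 in the stage comparison and 0.877 in the line comparison. Simulated genes of like level shared their spread, and no simulated change differed between the lines. With the real counts edgeR called 0 genes between the stages, so these rates do not carry over to them.

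Alternatives fixed before the data were examined were other filters, other scalings, limma on quantile normalized values, the cell line as a block, leaving out each library in turn, an estimated correlation in camera, and another pseudocount for the correlation of the lines' changes. DESeq2 1.42.0 and the limma fits on log2 CPM with a pseudocount of 1 or 0.1 and without the trend were added after the data were examined. Without 1 library, a stage has 1 library, and the spread comes from the pair of the other stage. Filters and scalings planned for FPKM were applied to CPM. Some counts cover reads of overlapping genes: BEST1 had 0.672 to 0.792 times the count of FTH1, the gene it overlaps. ALDOA, a major glycolytic gene, had only 6 to 28 counts, so low counts of genes with overlapping neighbours can come from the counting.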

Results

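RNA of trophoblast cells derived from 2 human embryonic stem cell lines, H9 and ENVY, was sequenced on day 3 of BAP differentiation and on day 15, after further culture under trophoblast stem cell conditions. Each line gave 1 library per stage, so each stage held 2 libraries, and the spread within a stage was the spread between the 2 lines. Total counts were 8327169 for ENVY and 10350354 for H9 at day 3, and 8910726 for ENVY and 8391317 for H9 at day 15. Between 18164 and 19020 genes had at least 1 count in a library, and 15082 genes passed the expression filter. A count of 0 allowed a level of up to 0.385 CPM in the library where 1 count weighed most, for counting error only. The series title also names injection of such cells into mouse blastocysts, and its design text names undifferentiated stem cells, neither of which was analysed here.

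The libraries of H9 and ENVY lay close together at day 3 and far apart at day 15. Across genes, the Pearson correlation of log2 expression was 0.954 between the day 3 libraries and 0.820 between the day 15 libraries. The ENVY day 15 library correlated slightly more with the day 3 libraries, at 0.839 for ENVY and 0.826 for H9. At day 3, 1449 genes differed at least 2-fold between the lines and 68 at least 8-fold. At day 15 the numbers were 4797 and 771. The first principal component held 60.6% of the variance. It put the day 3 libraries at -65.1 for ENVY and -72.7 for H9, and the day 15 libraries at 19.6 for ENVY and 118 for H9. The next component, with 31.4%, put ENVY day 15 at -95.2 and H9 day 15 at 45.1, with the day 3 libraries between them at 23.4 and 26.8.

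The stage comparison asked which genes differed between day 3 BAP cultures and day 15 trophoblast stem cell cultures. In both lines, HSD3B1, CGA and PSG5 stood far higher at day 15, and ESRG, TUNAR and SOX2 stood far lower. HSD3B1, which encodes the placental 3-beta-hydroxysteroid dehydrogenase (chromosome 1, 119507203 to 119515058, GRCh38), was at 0.113 ± 0.159 CPM at day 3 and 278 ± 149 CPM at day 15 (SD, n = 2). ESRG, a long non-coding RNA of pluripotent cells (chromosome 3, 54632124 to 54639857), was at 547 ± 149 CPM at day 3 and 0.341 ± 0.482 CPM at day 15. SOX2, a pluripotency transcription factor (chromosome 3, 181711925 to 181714436), was at 90.6 ± 30.7 CPM at day 3 and 0.512 ± 0.723 CPM at day 15. No gene passed edgeR's quasi-likelihood test over all genes, where the smallest Benjamini-Hochberg adjusted p was 0.157, so values and no verb of change are given for single genes.

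Among the 12 genes with the largest differences towards day 15, several are known from placenta. CGA, the common alpha subunit of the glycoprotein hormones, had 2 and 6 counts at day 3 in ENVY and H9, and 138 and 4796 counts at day 15. PSG5, a pregnancy-specific glycoprotein, was at 0 and 1 counts at day 3 and at 391 and 640 counts at day 15. SIGLEC6, a sialic acid receptor of trophoblast, was at 1.43 ± 0.528 CPM at day 3 and 195 ± 188 CPM at day 15. IGF2, an imprinted growth factor gene, was at 1.17 ± 1.18 CPM at day 3 and 272 ± 249 CPM at day 15. TGM2, a transglutaminase, was at 8.18 ± 7.12 CPM at day 3 and had 14794 counts in ENVY and 5780 in H9 at day 15. MVP, the major vault protein, differed least between the lines at day 15 among these 12, with 275 ± 9.84 CPM against 2.50 ± 2.19 CPM at day 3. The other named genes were IFI6, an interferon-induced gene, the gap junction gene GJA5, the scavenger receptor gene OLR1, the peptidase gene DPP4, and FYB1, whose log2 changes by edgeR were 7.92, 7.36, 7.20, 8.16 and 10.39.

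The 12 genes with the largest differences towards day 3 included several expressed in pluripotent cells. TUNAR, a long non-coding RNA, had 1556 and 2402 counts at day 3 in ENVY and H9 and 0 counts in both day 15 libraries. PKDCC, a secreted kinase gene (chromosome 2, 42048021 to 42058517), was at 827 ± 25.5 CPM at day 3 and 5.72 ± 1.56 CPM at day 15. Its log2 change of -7.17 had the smallest standard error of the 24 named genes, 0.42, and an edgeR adjusted p of 0.157. APELA, which encodes a peptide ligand of the apelin receptor, was at 233 ± 108 CPM at day 3 and 0.968 ± 0.0822 CPM at day 15. SLC7A3, a cationic amino acid transporter gene, was at 679 ± 215 CPM at day 3 and 4.90 ± 6.57 CPM at day 15. The log2 changes by edgeR of PCAT14, GALNT17, DIO2 and CXCL14 were -8.56, -7.54, -6.70 and -7.63. The skeletal muscle actin gene ACTA1 had 878 and 1719 counts at day 3 and 1 and 3 counts at day 15, and RHBDL3 had 608 and 1085 counts at day 3 and 0 counts in both day 15 libraries.

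Over all 15082 genes, 0 passed edgeR's test after Benjamini-Hochberg adjustment, and 2745 had an unadjusted p under 0.05, 1515 of them higher and 1230 lower at day 15, where chance alone gives 754.1. DESeq2, an alternative added after the data were examined, called 1539 genes, 960 higher and 579 lower, and these included all 24 genes named above. That overlap is no support, since the 24 were picked from these same counts for large differences alike in both lines. With the cell line as a block, edgeR again called 0 genes, with a smallest adjusted p of 0.281 and 1892 genes at an unadjusted p under 0.05. The count was 3307 without the ENVY day 15 library and 1328 without the H9 day 15 library, and 0 without either day 3 library. In each of these fits a stage has 1 library, which is assumed to vary like the pair of the other stage. The day 3 pair lay far closer together than the day 15 pair. Without either day 3 library, the excess over chance at an unadjusted p under 0.05 was also gone. The smallest p that an exact permutation test of 2 against 2 libraries can give is 0.333.

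Several gene lists fixed before the data were examined moved against the other genes by camera, but only at its preset correlation. For lists, rose and fell below give camera's direction in that test. Of 31 lists tested with camera at a preset correlation of 0.01, 17 passed after Benjamini-Hochberg adjustment, and none passed with an estimated correlation, where camera's adjusted p ran from 0.582 to 0.929. Among the 17 lists the estimated correlation ran from -0.0636 for stratified epithelium to 0.417 for FGF and ERK targets. No member of any list passed edgeR's test over all genes. The counts of members given here are therefore those adjusted over the list alone, with a gene on several lists counted in each. Summed over the 31 lists there were 83 such members, against 4 and 7 without the ENVY or the H9 day 3 library and 341 and 267 without the ENVY or the H9 day 15 library. Of the 17 lists, 7 kept camera's call without each library and in every other fit at the preset correlation. The other 10 lost it without at least 1 library, where again the pair of the other stage alone gives the spread. As examples of each list, the members with the highest mean CPM are given, unless said otherwise.

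The primed pluripotency list fell, and the trophoblast stem cell and syncytiotrophoblast lists rose. The primed pluripotency list fell (camera adjusted p = 8.56e-11, and adjusted p = 0.582 with an estimated correlation), and 12 of its 23 tested members fell by edgeR adjusted over the list alone, against 11 with cell line as a block, 0 without either day 3 library and 20 without the ENVY day 15 library. Of this list, LIN28A, an RNA-binding protein gene, stood at 2569 and 2598 CPM at day 3 in ENVY and H9 and at 403 and 73.0 CPM at day 15. DNMT3B, a DNA methyltransferase gene, stood at 591 and 713 CPM at day 3 and at 70.1 and 378 CPM at day 15. The cytotrophoblast and trophoblast stem cell list rose (camera adjusted p = 0.000402, and adjusted p = 0.582 with an estimated correlation). Adjusted over the list alone, 12 of its 36 tested members passed edgeR's test. The count was 4 with cell line as a block, 0 without either day 3 library, and 25 and 23 without the ENVY or the H9 day 15 library. KRT18, a simple epithelial keratin gene, stood at 2216 and 2359 CPM at day 3 in ENVY and H9 and at 4590 and 3647 CPM at day 15, and PEG10, an imprinted retrotransposon-derived gene, at 651 and 460 CPM and then at 714 and 3399 CPM. The members ITGB4 and LRP2, chosen after their values were seen, stood at 13.4 and 7.57 CPM and at 210 and 166 CPM at day 3, and at 380 and 714 CPM and at 1174 and 1913 CPM at day 15.

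The syncytiotrophoblast list, genes of the fused outer layer of the placenta, rose as well (camera adjusted p = 2.66e-11, and adjusted p = 0.582 with an estimated correlation). Adjusted over the list alone, 6 of its 31 tested members passed edgeR's test. The count was 13 with cell line as a block, 4 without either day 3 library, and 13 and 10 without the ENVY or the H9 day 15 library. In 17 members both lines were at least 2-fold higher at day 15, and in 0 members both lines were at least 2-fold lower. SLC2A1, a glucose transporter gene, stood at 264 and 297 CPM at day 3 in ENVY and H9 and at 258 and 1230 CPM at day 15, and ERVW-1, which encodes the fusogen syncytin-1, at 1.46 and 0.479 CPM and then at 3.64 and 657 CPM. Reads of the CGB and PSG families and of the HLA genes can be shared between near-identical copies, so the split between members of those families is uncertain. The list of trophoblast transcription factors rose (camera adjusted p = 0.0363, and adjusted p = 0.644 with an estimated correlation), with 0 of 35 members adjusted over the list alone and 2 with cell line as a block. GATA3 and ARID3A, its most abundant members, stood at 406 and 388 CPM and at 318 and 222 CPM at day 3 in ENVY and H9, and at 221 and 859 CPM and at 316 and 729 CPM at day 15. Without the H9 day 15 library this list's direction turned, with a camera adjusted p of 0.395. Adjusted over the list alone, 28 and 15 members passed without the ENVY or the H9 day 15 library. Its call was also lost with the stricter filter, with a camera adjusted p of 0.101, and in the limma fits, with 0.0823 to 0.151.

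The lists of interferon-stimulated genes and of stratified epithelium also rose against the other genes. Of the interferon-stimulated genes, 13 of 22 tested members rose by edgeR adjusted over the list alone, against 0 without either day 3 library (camera adjusted p = 2.02e-10, and adjusted p = 0.582 with an estimated correlation). IFITM3 stood at 121 and 144 CPM at day 3 in ENVY and H9 and at 282 and 768 CPM at day 15, and IFI6 at 2.14 and 2.78 CPM and then at 86.4 and 1116 CPM. Of the epidermal keratinocyte and stratified epithelium list, 8 of 16 tested members passed edgeR's test adjusted over the list alone, against 7 with cell line as a block, 0 without the ENVY day 3 library and 3 without that of H9 (camera adjusted p = 6.71e-06, and adjusted p = 0.582 with an estimated correlation). LAMC2, a laminin chain gene, stood at 31.3 and 25.8 CPM at day 3 and at 655 and 73.6 CPM at day 15, and PKP1, a plakophilin gene chosen after its values were seen, went against the list, with 17.9 and 23.2 CPM at day 3 and 0.114 and 0 CPM at day 15. The list of HLA class I and antigen presentation genes rose (camera adjusted p = 0.00672, and adjusted p = 0.582 with an estimated correlation), with 2 of 15 members adjusted over the list alone and 0 with cell line as a block. Its call was lost without the ENVY day 15 library, with a camera adjusted p of 0.864, and with the stricter filter, with 0.113. Its members CALR and PDIA3, endoplasmic reticulum chaperones of peptide loading, stood at 695 and 766 CPM and at 455 and 582 CPM at day 3, and at 1018 and 1106 CPM and at 623 and 699 CPM at day 15.

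The cell cycle and BMP target lists fell against the other genes. In the cell cycle and DNA replication list both lines were lower at day 15 for 32 of 35 members (camera adjusted p = 1.74e-07, and adjusted p = 0.617 with an estimated correlation), with 1 member adjusted over the list alone and 0 with cell line as a block. TOP2A, a DNA topoisomerase gene, stood at 363 and 372 CPM at day 3 in ENVY and H9 and at 295 and 198 CPM at day 15, and MCM4, of the replicative helicase, at 382 and 448 CPM and then at 150 and 177 CPM. The BMP target list fell (camera adjusted p = 0.0177, and adjusted p = 0.582 with an estimated correlation), with 4 of 23 members adjusted over the list alone. That count was 0 without either day 3 library, and 16 and 10 without the ENVY or the H9 day 15 library. Between the stages 3 members were higher in ENVY and lower in H9, and 7 the reverse, and without the ENVY day 15 library the list's camera adjusted p was 0.145. Its member ID1, an inhibitor of bHLH factors, stood at 799 and 715 CPM at day 3 and at 110 and 48.7 CPM at day 15, whereas GATA3 was higher at day 15 in H9 and lower in ENVY. The neural and neuroectoderm list fell (camera adjusted p = 0.00159, and adjusted p = 0.617 with an estimated correlation), with 1 of 19 members adjusted over the list alone and 2 with cell line as a block. Its call was lost without the ENVY day 3, the H9 day 3 or the H9 day 15 library, with camera adjusted p of 0.145, 0.147 and 0.0759. Its member NES stood at 237 and 590 CPM at day 3 and at 353 and 7.44 CPM at day 15, and TUBB3 at 117 and 250 CPM and then at 320 and 121 CPM. The amnion list fell (camera adjusted p = 0.0181, and adjusted p = 0.617 with an estimated correlation), with 1 of 30 members adjusted over the list alone and 2 with cell line as a block, and without the H9 day 15 library its direction turned, with a camera adjusted p of 0.664. CTSV, a cathepsin gene of this list, stood at 1272 and 843 CPM at day 3 and at 137 and 183 CPM at day 15, while EPAS1, a hypoxia-inducible factor gene, stood at 536 and 266 CPM and then at 989 and 2496 CPM.

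The remaining 6 lists past camera's threshold rose with all 4 libraries, and only the immediate early list kept its call without each of them. Camera's adjusted p was 0.00138 for cholesterol synthesis, 0.00170 for FGF and ERK targets, 0.00235 for immediate early and heat shock genes, 0.00978 for cyclin-dependent kinase inhibitors and p53 targets, 0.0283 for glycolysis and hypoxia and 0.0332 for unfolded protein and amino acid stress, and with an estimated correlation the adjusted p of these lists lay at 0.617 or 0.624. Adjusted over the list alone, edgeR's test was passed by 1 of 24, 2 of 25, 2 of 18, 0 of 24, 0 of 30 and 0 of 20 members of these lists in the same order. With cell line as a block the cholesterol list had 0, the FGF and ERK list 1 and the p53 list 1. Without the ENVY day 15 library camera's adjusted p was 0.145 for the cholesterol list and 0.820 for the FGF and ERK list. Without the H9 day 15 library it was 0.790 for the p53 list, 0.104 for glycolysis and 0.410 for unfolded protein. Without the ENVY day 3 library these were 0.152, 0.205 and 0.229. The glycolysis call was also lost with the stricter filter, with a camera adjusted p of 0.0547, and with quantile normalized values it was 0.0971, against 0.0670 for unfolded protein. HSPA5, an endoplasmic reticulum chaperone gene of the unfolded protein list, stood at 483 and 696 CPM at day 3 in ENVY and H9 and at 952 and 1109 CPM at day 15. DHCR24, of cholesterol synthesis, stood at 579 and 701 CPM at day 3 and at 806 and 272 CPM at day 15. DUSP5, of the FGF and ERK list, had 80 and 208 counts at day 3 and 2049 and 4218 counts at day 15. CCND1, of the same list, went opposite ways, with 71.8 and 186 CPM at day 3 and 262 and 46.4 CPM at day 15. The median difference of the FGF and ERK list was 2.18 in ENVY and -0.30 in H9. Of its 25 members, 13 were higher at day 15 in ENVY and lower in H9.

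For 14 of the 31 lists camera's test was not passed. Camera's adjusted p was 0.0696 for WNT beta-catenin targets and for DNA methylation and chromatin regulators, 0.110 for extravillous trophoblast, 0.166 for replication-dependent histones, 0.217 for Hippo targets, 0.218 for imprinted genes, 0.220 for mesoderm, 0.222 for simple epithelial keratins and junctions, 0.329 for oxidative phosphorylation, 0.401 for naive pluripotency, 0.516 for mesenchyme, 0.570 for NODAL and TGF-beta targets, 0.680 for ribosomal proteins and 0.838 for endoderm. Some members of these lists still passed edgeR's test adjusted over the list alone: 6 of 28 extravillous trophoblast genes, 5 of 21 DNA methylation and chromatin regulators, 3 of 20 imprinted genes, 2 of 7 naive pluripotency genes, 1 of 22 WNT targets and 1 of 16 NODAL targets, and none did without either day 3 library. With cell line as a block the DNA methylation list had 0, the imprinted list 2, the naive list 0 and the NODAL list 0, and the extravillous, WNT and imprinted lists then passed camera's test, with adjusted p of 0.04998, 0.0243 and 0.0396. With the block and an estimated correlation none of these 3 passed (camera adjusted p = 0.655 for each). TIMP3, a metalloproteinase inhibitor gene of the extravillous list, stood at 63.9 and 77.0 CPM at day 3 in ENVY and H9 and at 765 and 1666 CPM at day 15, and FN1, fibronectin, at 853 and 1595 CPM and then at 1765 and 145 CPM.

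Marker genes chosen before the data were examined separated into those that differed alike in both lines and those that did not. TP63, the transcription factor of villous cytotrophoblast, was at 1.25 ± 1.09 CPM at day 3 and 43.0 ± 20.5 CPM at day 15 (SD, n = 2), and the laminin receptor gene ITGA6 was at 81.8 ± 25.2 CPM and then at 384 ± 70.4 CPM. SDC1, a syndecan gene of syncytiotrophoblast, was at 9.33 ± 7.94 CPM at day 3 and 151 ± 117 CPM at day 15, and HLA-G had 1 and 0 counts at day 3 and 16 and 262 counts at day 15 in ENVY and H9. POU5F1 had 10 and 200 counts at day 3 and 0 and 1 counts at day 15, NANOG had 3 and 10 counts and then 0 counts in both libraries and was below the filter, and CDX2 had 44 and 159 counts and then 23 and 2 counts. ISL1, an amnion marker, had 220 and 485 counts at day 3 and 61 and 0 counts at day 15. GATA3, TFAP2C and TEAD4, trophoblast transcription factors, were lower at day 15 in ENVY and higher in H9, and ELF5 stayed at 28 counts or fewer in every library. TFAP2C went from 1669 to 364 counts in ENVY and from 2465 to 3121 counts in H9. KRT7 and GABRP went the other way, higher at day 15 in ENVY and lower in H9, and GABRP, a GABA receptor subunit gene of amnion, went from 1690 to 2590 counts in ENVY and from 563 to 4 counts in H9. The edgeR adjusted p of these markers lay between 0.172 for ITGA6 and 0.984 for TFAP2C.

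**Figure D1:**
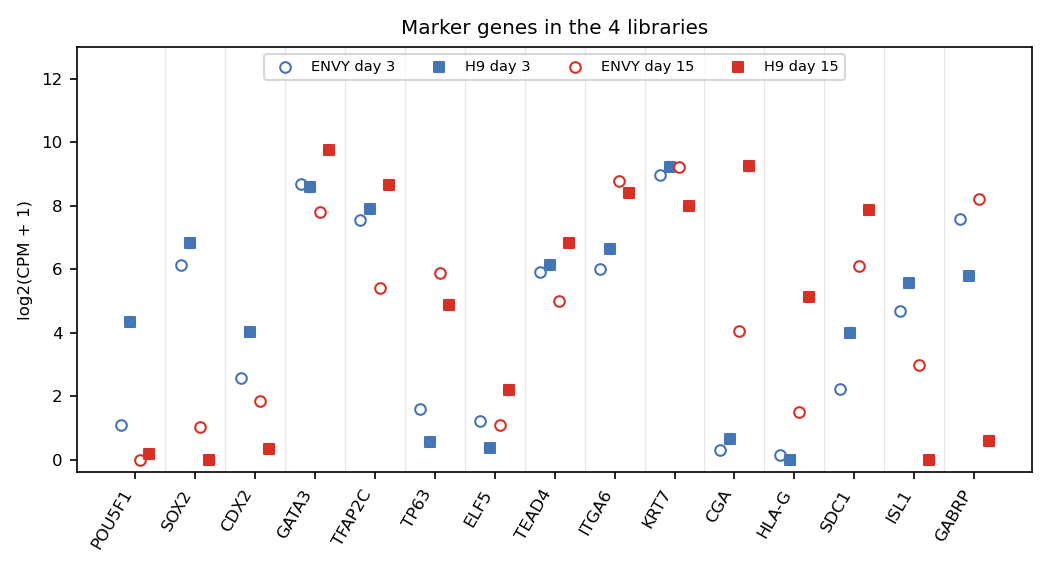
Expression of 15 marker genes as log2(CPM + 1) on the vertical axis, with 1 point per library, circles for ENVY, squares for H9, blue for day 3 and red for day 15. TP63, ITGA6, CGA, HLA-G and SDC1 stand higher in both day 15 libraries than in both day 3 libraries, and GABRP stands at 294 CPM in ENVY and 0.513 CPM in H9 at day 15.

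The comparison of the lines asked which genes differed between H9 and ENVY across both stages. GDF15, a stress-responsive member of the TGF-beta family (chromosome 19, 18386158 to 18389176), had 0 and 10 counts in ENVY at days 3 and 15 and 94 and 2271 counts in H9. PLSCR1, a phospholipid scramblase gene, had 33 and 53 counts in ENVY and 972 and 2617 counts in H9, and ANK1, an ankyrin gene, had 20 and 18 counts in ENVY and 490 and 2037 counts in H9. The zinc finger genes ZNF107 and ZNF440 had 0 counts in both ENVY libraries, with 251 and 200 counts and with 207 and 237 counts in H9. In the other direction, CRYZ, a quinone reductase gene, had 535 and 1138 counts in ENVY and 0 and 24 counts in H9. RNASE1 had 170 and 1965 counts in ENVY and 11 and 0 counts in H9, C9orf64 had 229 and 335 counts against 0 in both H9 libraries, SLC30A8 had 142 and 166 counts against 0 in both H9 libraries, and GABRP was named by this rule too. With the stage taken out, 0 of the 15082 genes passed edgeR's test (smallest adjusted p = 0.999). An unadjusted p under 0.05 was reached by 342 genes, where chance alone gives 754.1. In this fit the only residual is the change of the lines' difference between the stages. A difference seen at a single stage thus counts as spread, and the 0 calls do not show that the lines are alike. DESeq2, added after the data were examined, called 67 genes, 42 higher in H9 and 25 higher in ENVY.

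Each line's difference between stages was then set against that of the other line. Across 15082 genes, the day 15 minus day 3 difference in log2(CPM + 1) had a Pearson correlation of 0.425 and a Spearman correlation of 0.390 between the lines, and 63.8% of genes had the same sign. Genes are not independent replicates, and with 1 library per line and stage the difference between the lines has no test. At least 2-fold, 1109 genes were higher at day 15 in both lines and 1051 lower in both. ENVY was higher and H9 lower for 412 genes, and the reverse held for 109 genes.

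**Figure D2:**
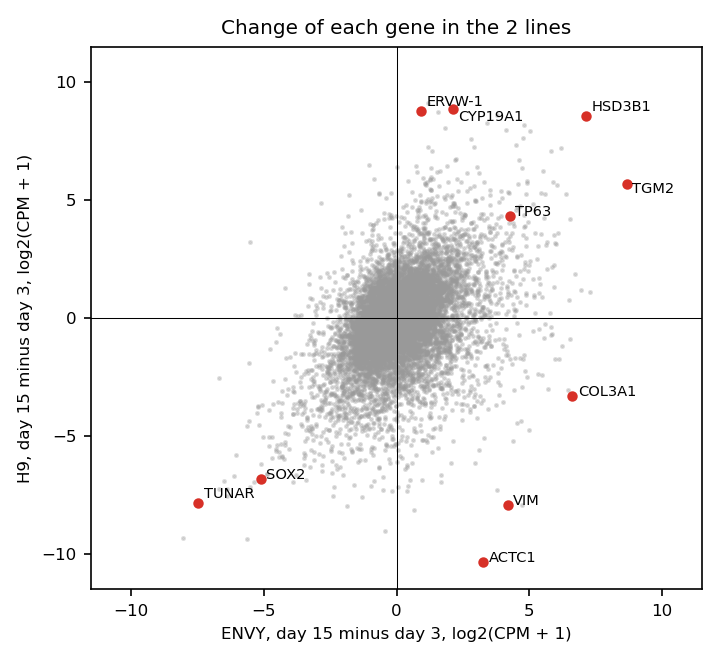
Each point is 1 of 15082 genes, with the day 15 minus day 3 difference in log2(CPM + 1) in ENVY on the horizontal axis and in H9 on the vertical axis, and named genes in red. TUNAR and SOX2 lie low in both lines, HSD3B1, TGM2 and TP63 high in both, and VIM, ACTC1 and COL3A1 high in ENVY and low in H9.

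Lists of mesenchyme, amnion and syncytiotrophoblast genes stood far apart between the lines at day 15. The median difference of the mesenchyme and fibroblast list was 1.98 in ENVY and -1.65 in H9, and that of the amnion list was 0.40 in ENVY and -2.85 in H9. The syncytiotrophoblast list had a median of 1.71 in ENVY and 4.30 in H9, both above all 10000 random lists matched on expression, which describes these libraries and is no test. At day 15 the H9 minus ENVY median was -3.40 for mesenchyme, -2.14 for amnion and 2.25 for syncytiotrophoblast, against 1.16, 0.22 and 0.00 at day 3. At day 3, 14 mesenchyme members stood at least 2-fold higher in H9. COL1A2, a fibrillar collagen gene, stood at 1687 CPM in ENVY and 420 CPM in H9 at day 15, and SPARC, a matrix glycoprotein gene, at 1108 and 22.3 CPM. By a rule chosen after the data were examined, the genes with the largest differences at day 15 were listed for each direction. Higher in H9 were ERVFRD-1, which encodes the fusogen syncytin-2, with 4374 counts against 11 in ENVY, ERVW-1 with 5125 against 32, and the steroid synthesis genes CYP19A1 with 3955 against 42 and CYP11A1 with 3026 against 32. NOS2, SLC52A1, SIGLEC5, GDF15, ATP6V1B1 and ANK1 completed the 10. Higher in ENVY were ACTC1, cardiac actin, with 21728 counts against 1 in H9, VIM, vimentin, with 8957 against 4, the osteopontin gene SPP1 with 10248 against 4, the tenascin gene TNC with 7891 against 13, and COL3A1 with 2518 against 2. At day 3 these 5 stood higher in H9. They had 2282 counts in ENVY and 15266 in H9 for ACTC1, and 492 and 3799 for VIM, 381 and 3812 for SPP1, 910 and 1346 for TNC, and 17 and 118 for COL3A1. ADAMTS9, IGFBP5, KIF1A, RNASE1 and IGFBP2 completed the 10, and reads of VIM and of its antisense partner VIM-AS1 cannot be told apart here.

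**Figure D3:**
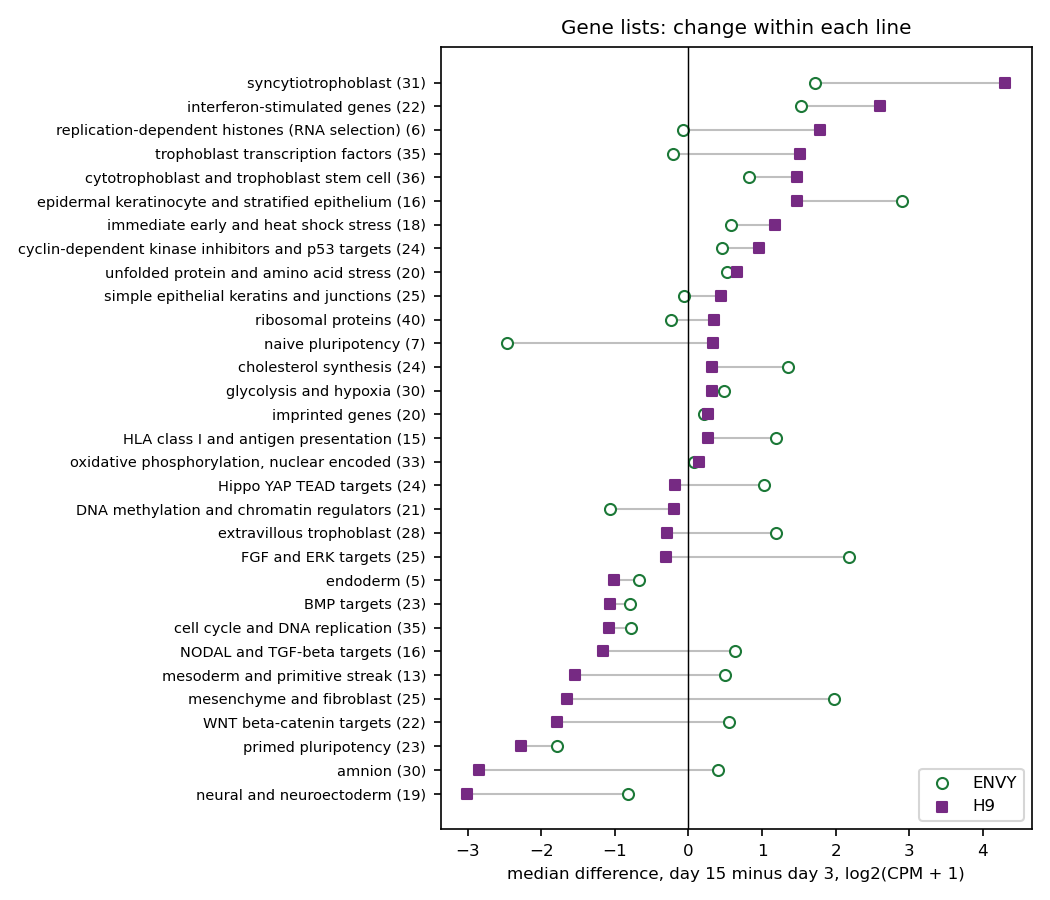
Median difference of each gene list between day 15 and day 3 in log2(CPM + 1), with circles for ENVY, squares for H9 and the number of tested members in brackets. The syncytiotrophoblast list stands at 1.71 in ENVY and 4.30 in H9, and the mesenchyme list at 1.98 and -1.65.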

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

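In this part the tests of the day 15 difference and of stress, and the comparison of the further p53 list with the other lists, were chosen after the results were seen, while the tests of scaling and of a further p53 list were written beforehand. Several results went in opposite directions in H9 and ENVY between day 3 and day 15, and these differences were not tested, since each line has 1 library per stage. Values are the H9 change minus the ENVY change in log2(CPM + 1). Some opposite signs rest on a small change in 1 line. In ENVY the change was -0.14 for ELF5, 0.27 for KRT7, -0.05 for simple epithelial keratins and -0.08 for histones. In H9 it was -0.18 for Hippo targets. Among the markers the difference was 2.02 for GATA3, 2.91 for TFAP2C, 1.97 for ELF5, 1.63 for TEAD4, -1.50 for KRT7 and -5.81 for GABRP. Among list medians it was 2.80 for naive pluripotency, 1.72 for trophoblast transcription factors, 1.86 for replication-dependent histones, 0.57 for ribosomal proteins and 0.50 for simple epithelial keratins and junctions. It was -1.48 for extravillous trophoblast, -3.25 for amnion, -2.04 for mesoderm and primitive streak, -3.63 for mesenchyme and fibroblast, -1.80 for NODAL and TGF-beta targets, -2.48 for FGF and ERK targets, -2.34 for WNT beta-catenin targets and -1.21 for Hippo targets.

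The day 15 libraries of H9 and ENVY differed at least 8-fold in 771 genes, against 68 at day 3, with 547 higher in ENVY. Depth is argued against, since the larger total was 1.06 times the smaller at day 15 and 1.24 times at day 3. Cells left over from day 3 are argued against for most of the genes 8-fold higher in ENVY, since 77.0% of them stood above their ENVY day 3 level. These genes were picked on the same ENVY day 15 value, which favours that outcome, and for the remainder leftover cells stay open. A difference between the lines already there at day 3 is argued against for most genes, since 13.6% differed at least 2-fold in the same direction at day 3. Dilution of H9-like cells by another cell type stays open: over 21 syncytiotrophoblast genes at 20 CPM or more in H9 at day 15 the log2 ratio had an interquartile range of 4.67, but 1 common factor holds only if the other cells lack these genes, and their profile was not measured. A difference between the lines, or between the cultures, in the cell types formed may remain, and with 1 library per line and stage these were not tested apart.

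The list of p53 targets and cyclin-dependent kinase inhibitors was noticed among the 31 lists after their medians were seen. Its median stood lower in ENVY than in H9, by 0.90 at day 3 and 1.88 at day 15. Of 24 tested members, 9 stood at least 2-fold higher in H9 at both days. At day 15, 4 members stood at least 2-fold higher in ENVY, and the inhibitor genes CDKN2A and CDKN2B were higher in ENVY. CDKN1A had 3 and 698 counts in ENVY against 442 and 3886 in H9. Library scaling is argued against, since the day 3 median was at least 0.848 under every scaling tried. Stress in the H9 cultures stays open, because the stress lists' median was at most 0.350 of the p53 list's but their members went both ways. A further list of 30 p53 targets, none in the first list, had medians of 0.70 and 1.12 over 29 tested genes, and both stood at percentile 100 of matched random lists, which describes these libraries and is no test. Lower p53 target activity in ENVY stays open, since the unfolded protein list also stood high at both days, at percentiles 99.9 and 98.5. At day 3, 6 of the 30 other lists stood at percentile 100, but at day 15 these 6 stood at 0 to 15.3. TP53 itself had 1016 and 458 counts in ENVY and 1324 and 556 in H9. The syncytiotrophoblast list, which shares GDF15 with the p53 list, also stood higher in H9 at day 15. Its median difference was 2.25 there, against 0.00 at day 3, and the differences of these lists at day 15 were not tested apart.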

How the results depend on the processing

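The limma fits on log2 CPM without quantile normalization and DESeq2 were chosen after the data were examined. The count of 0 genes between stages was the same with the stricter filter, with totals only, with median ratio scaling, with cell line as the replicate block (0 genes) and in the limma fits on log2 CPM with either pseudocount or no trend. It was 40 with no filter, 2 with limma on quantile normalized values and 1539 with DESeq2, and without 1 library it ranged from 0 to 3307; the cause was not tested. Between the lines only DESeq2 differed, with 67 genes; leaving out a library leaves no residual degrees of freedom there, and no such value was possible for the correlation of the lines' changes. The 17 lists past camera's threshold became 14 to 20 under the other settings, 20 with cell line as a block and 15 to 18 without 1 library, and 0 with an estimated correlation. The correlation across genes of 0.425, with a bootstrap SD of 0.0101 over genes, moved to 0.442 with a pseudocount of 0.1, 0.389 with no filter, 0.456 with the stricter filter and 0.441 with quantile normalized values. Without the H9 day 15 library the trophoblast transcription factors and amnion lists changed direction, with camera adjusted p of 0.395 and 0.664. No single marker that changed sign had passed with all 4 libraries. Without the H9 day 15 library TFAP2C had an edgeR adjusted p of 0.0220, and without that of ENVY GABRP had 0.0204, but there the spread came from the day 3 pair alone and the lone day 15 library is assumed to vary like it, so neither is taken as a call. GATA3 was at -0.016 with quantile values. TFAP2C was at -0.083 with totals only, -0.71 with the block, -0.87 with quantile values, -0.70 with limma at a pseudocount of 1 and without the trend, and -0.71 at 0.1. TEAD4 was at -0.12 with the block, -0.27 with quantile values, -0.11 with limma at a pseudocount of 1 and without the trend, and -0.12 at 0.1. GABRP was at -2.56 with the block, -2.13 with quantile values, -2.28 with limma at a pseudocount of 1 and without the trend, and -2.92 at 0.1. Without 1 library in turn, the log2 change ranged from -0.83 to 1.15 for GATA3, -2.34 to 0.95 for TFAP2C, -1.06 to 0.85 for TEAD4, -1.08 to 0.14 for KRT7 and -7.82 to 1.46 for GABRP, and camera's adjusted p from 0.000121 to 0.395 for trophoblast transcription factors and from 2.37e-08 to 0.664 for amnion; the cause was not tested. Scaling moved the median change of all genes from 0.01 to -0.10 at most. The block changed no camera call and no count of calls other than those given with the results. In the simulated stage comparison edgeR recovered 18 of 100 genes changed 4-fold and 99 of 100 changed 64-fold. With the real counts it called 0 genes, although PKDCC had a log2 change of -7.17. Simulated genes of like level shared their spread, so these rates are no guide to the power here, and 4-fold changes can be missed.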

Other observations

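The genes named here were chosen after their values were seen, and none passed edgeR's test over all genes. Imprinted genes included large differences in both directions. DLK1 stood at 60.4 and 29 CPM at day 3 in ENVY and H9 and at 0.227 and 0.256 CPM at day 15, while H19 stood at 0.113 and 0 CPM and then at 3.30 and 54.4 CPM, and PLAGL1 at 0.563 and 1.05 CPM and then at 12.6 and 11 CPM. The cyclin-dependent kinase inhibitor genes CDKN2A and CDKN2B were higher at day 15 in both lines, at 2.03 and 3.26 CPM and then 98.4 and 21.9 CPM for CDKN2A, and at 0.563 and 1.92 CPM and then 28 and 5.0 CPM for CDKN2B. CCNE1 went against the direction of the cell cycle list, with 21.8 and 24.9 CPM at day 3 and 52.4 and 195 CPM at day 15.

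Some genes were listed at 0 in both libraries of 1 line and at 50 counts or more in both libraries of the other. There were 10 such genes at 0 in ENVY, 6 of them zinc finger genes with ZNF symbols, which make up 484 of the 15082 tested genes, and 2 at 0 in H9, C9orf64 and SLC30A8. From these counts 1 gene that is absent from some genomes was left out, and whether the other loci are intact in these lines was not tested. ZNF433, ZNF440, ZNF69 and ZNF700 lie between 11814273 and 12035679 on chromosome 19 (GRCh38). That interval was drawn around these genes, which were picked for 0 counts in ENVY, and genes beside it were not examined. All 7 tested genes overlapping it were at 0 counts in both ENVY libraries. The other 3 were ZNF439, with 27 and 17 counts in H9 at days 3 and 15, ZNF763, with 88 and 10, and ZNF433-AS1, with 77 and 20. ZNF107 and ZNF138 lie between 64666133 and 64860823 on chromosome 7, an interval that holds no other tested gene. Over all tested genes, 1.42% were at least 2-fold higher in H9 at both days, which is no yardstick for intervals drawn around picked genes. MGMT, a DNA repair gene, had 2 and 0 counts in ENVY and 133 and 207 counts in H9. CHCHD2, a mitochondrial protein gene, had 253 and 506 counts in ENVY at days 3 and 15 and 363 and 0 counts in H9.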
